A study of Arabidopsis thaliana with 6 samples.

How the data were processed

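Total RNA from whole plants of Arabidopsis thaliana at growth stage 1.04 was labelled with biotin and hybridised to ATH1 oligonucleotide arrays, per the labels. An ATH1 array carries probe sets, groups of short oligonucleotides that together measure a transcript. The labels give 3 arrays of the wild type, accession Col0, and 3 arrays of a line labelled as an atm mutant. ATM is the protein kinase that starts much of the response to DNA double-strand breaks. The labels call the mutant atm in the titles, ATM1 in the source name and AtATM3 mutant in the genotype. The group was taken from the titles, and the allele stays unsure. The title of the series speaks of X-ray inducible transcripts that depend on ATM, but the labels state no irradiation, dose or time after treatment, so the groups were compared by genotype alone. Nothing in the labels says that the replicates came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.

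The authors deposited 1 signal intensity per probe set and array on a linear scale, made with MAS5 in GCOS per the submitters' processing notes. The scaling target, detection calls and filters were not given in the sources used here. On every array the mean of the deposited intensities, after trimming 2% of the probe sets at each end, was about 100, and all values were above 0. A single scaling factor per array of this kind leaves differences in the shape of the distribution between arrays in place, and low MAS5 signals are noisy on a log scale, so both were varied in alternatives. Array data have no read depth, and the number of arrays limits the precision.

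The deposited intensities were taken to log2 with no further scaling and no pseudocount. The 64 Affymetrix control probe sets were left out, as were probe sets that did not exceed the 40th percentile of their array on at least 3 of the 6 arrays, which left 13895 of 22746. The difference of atm mutant minus wild type was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without a block, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of adjusted p under 0.05. All p-values are two-sided. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so the tests rest on limma's model, which shares the spread across probe sets. Fold changes are ratios of geometric means. Where all 3 arrays of the dimmer group lay below the 20th percentile of their arrays, the fold change was computed with lower values raised to that percentile. That percentile is not a detection limit, so such a fold change is not a strict bound.

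Probe sets were named from the platform annotation, with symbols updated by gene ID through the RefSeq gene table of TAIR10.1. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were unnamed here. Of those with 1 gene, 13436 matched the reference by gene ID. Among the tested probe sets, 7454 had 1 gene, 280 had several and 6161 were unnamed here, and 7380 genes were represented. No gene was named from a probe set with several, and no coordinates were used. A gene with more than 1 probe set was represented by the one with the highest mean log2 signal. No gene with a called probe set had another probe set that differed in call.

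Before the data were examined, the tests, most alternatives, 15 gene lists of 265 members in all, and the rule for named genes were fixed. By that rule the text names ATM and XRI1, up to 12 genes with the largest fall and up to 12 with the largest rise among called genes whose groups did not overlap, and, where under 3 passed in a direction, the 5 with the smallest p in it as values. It also names from each list up to 6 called members, or up to 20 for the DNA damage list, or the 2 with the smallest p where none was called. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of the same family.

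Another 15 lists were added after the data had been examined. One is of ionising radiation loci, 30 locus codes recalled from general knowledge of published irradiation studies of this plant. These codes were written down before any comparison of the groups had been computed. Whether any of those studies drew on these same samples was not checked, so the list is not independent evidence of its direction. The other 14 lists hold the plastid-encoded genes and gene families found by searches of gene names. Those searches were also written before any comparison, but the choice of which lists to keep, and the trimming by hand of the repair and the cytochrome P450 lists, came after a first comparison had been seen.

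Alternatives were quantile normalization, median centring, no filter on dim probe sets, a filter at the 60th percentile, a floor at the 20th percentile, a pseudocount of the 40th percentile, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, each array left out in turn, and the mean of all probe sets of a gene. Chosen after seeing the data were a term for wild type replicate 1 and atm mutant replicate 2, which deviated together from their group means, and a fit to the other 4 arrays. The fit was tested on simulated data with the real means of the 13895 probe sets and the spreads that limma had shared across them. It recovered 64% of 50 changes of 1 on the log2 scale, 88% at 2, 96% at 3 and 100% at 4, with 13 false among 187 calls. The simulated noise was independent between probe sets and lacked the deviation that 2 arrays shared. More calls were made there than the 31 in the data, so these shares may be too high for the real fit. Camera was tested on 30 simulated lists lowered by 1 on the log2 scale and called 30, and called 0 of 30 lists with no change. Calls there were at an unadjusted p under 0.05 and the simulated genes were independent. This does not test lists whose members are correlated. Figures were drawn with matplotlib 3.10.9.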

Results

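Transcript levels were measured on ATH1 arrays in whole plants of Arabidopsis thaliana, in 3 wild type (Col0) samples and 3 samples labelled as an atm mutant, where ATM is the kinase that signals DNA double-strand breaks. The series asks which X-ray inducible transcripts depend on ATM. The labels give no irradiated and unirradiated pair, so the comparison that the samples allow is atm mutant against wild type. The deposited MAS5 signals had medians between 40.1 and 41.4 over the 6 arrays. In the annotation used here no probe set was named for ATM or for XRI1, a gene known for its induction by X-rays. Either gene may be measured by an unnamed probe set, so no level could be assigned to it here. The genotype was therefore not checked at its own transcript.

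Over all 6 arrays the transcripts that passed the test were few, and all were lower in the atm mutant. AT2G45460, which encodes a protein with a SMAD/FHA domain, fell from a signal of 338.5 ± 35.3 to 27.7 ± 0.849 (SD, n = 3 each), a log2 change of -3.61 (SE 0.13, limma adjusted p = 3.0e-05). AT5G48020, of the 2-oxoglutarate and iron-dependent oxygenase superfamily, fell from 897 ± 140 to 156 ± 8.10, a log2 change of -2.52 (SE 0.15, adjusted p = 0.000276). AT3G45730, of uncharacterised function, fell from 420.1 ± 70.8 to 85.2 ± 23.2, a log2 change of -2.32 (SE 0.21, adjusted p = 0.00547). In each of them the 3 mutant values lay below all 3 wild type values. The number of calls, 31 in this fit, depended on how the arrays were used. With array weights 73 probe sets (5 higher) were called, and 108 (16 higher) with a term for wild type replicate 1 and atm mutant replicate 2. Without those 2 arrays 233 (76 higher) were called. The last 2 fits were added after seeing the data. All 31 stayed lower in each of these fits, so the higher calls were other probe sets. Some of the higher calls with the term came from groups that overlapped.

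Another 6 named genes were lower. AT3G42860, which encodes a zinc knuckle protein, had a signal of 55.3 ± 5.24 in the wild type and 3.08 ± 0.897 in the atm mutant (SD, n = 3 each, limma adjusted p = 0.0136). All 3 mutant arrays were below their 20th percentile, and with values raised to that percentile it was 7.18-fold lower. AT1G59660, related to nucleoporins, had 48.5 ± 4.96 in the wild type and 2.76 ± 1.07 in the mutant (adjusted p = 0.0297). It was also below the 20th percentile on all 3 mutant arrays, and 6.29-fold lower with values raised to it. AT5G23910, which encodes a kinesin-like motor protein, fell by 2.70 on the log2 scale (SE 0.31, adjusted p = 0.0175). AT4G25580, related to the cold-acclimation protein CAP160, fell from 77.8 ± 3.47 to 18.6 ± 2.70, a log2 change of -2.07 (SE 0.19, adjusted p = 0.00547). AT1G23710 fell by 1.69 (SE 0.16, adjusted p = 0.00585) and AT3G14560 by 1.44 (SE 0.14, adjusted p = 0.00695) on the log2 scale.

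**Figure D1:**
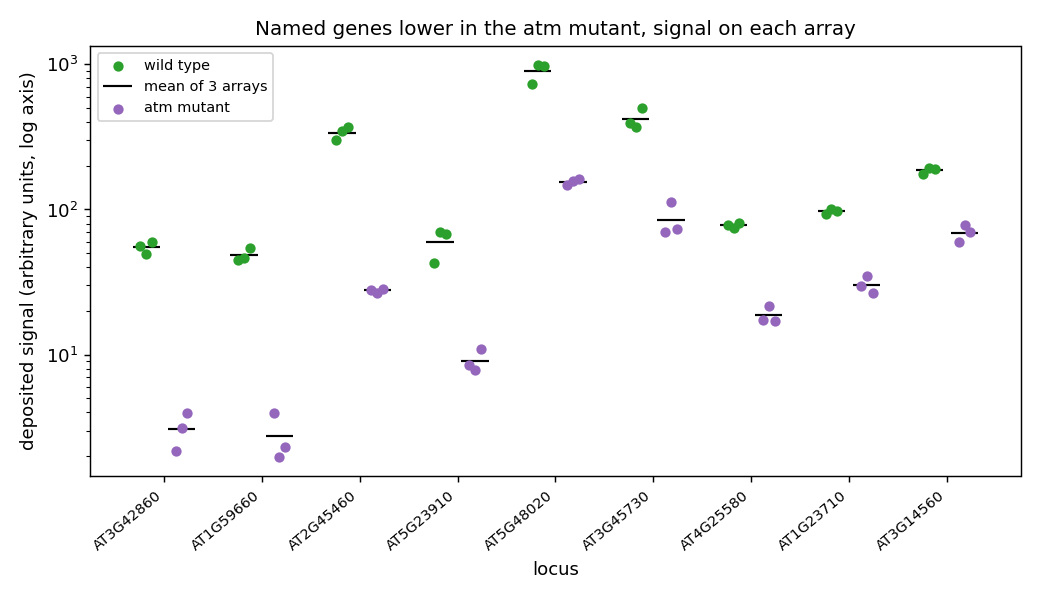
Deposited signal in arbitrary units on a log axis for the 9 named genes that were lower in the atm mutant, with 1 point per array and a line at the mean of the 3 arrays of each genotype. All 3 mutant points lie below all 3 wild type points for each gene, and AT2G45460 goes from a mean of 338.5 to 27.7.

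The calls of AT2G45460 and AT5G48020 held without any 1 of the 6 arrays, and so did that of AT3G45730. Over 18 alternatives the limma adjusted p was at most 0.00433 for AT2G45460 and 0.011 for AT5G48020. For AT3G45730 it reached 0.0981 with the replicate number as a block, the only alternative that ended its call. For the other 6 the calls did not hold without wild type replicate 2 or wild type replicate 3, where adjusted p ranged from 0.0734 to 0.762 over both. Leaving out wild type replicate 1 also ended the calls of AT3G42860 (adjusted p = 0.248) and AT1G59660 (0.373), leaving out atm mutant replicate 1 that of AT5G23910 (0.0747), and leaving out atm mutant replicate 3 those of AT1G59660 and AT3G14560 (both 0.0561). Sizes depended on the treatment of low values: with a pseudocount of the 40th percentile the log2 change was -1.50 for AT3G42860, -1.39 for AT1G59660, -1.30 for AT5G23910, -1.23 for AT4G25580 and -2.77 for AT2G45460.

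Over all 13895 probe sets tested, limma called 31, and 31 of 31 were lower in the atm mutant. Of these 9 had 1 named gene, 1 had several and 21 were unnamed here. The geometric mean fell between 2.18-fold and 51.4-fold, and 20 of the 31 fell by at least 4-fold. The groups did not overlap in any of the 31, which passing this threshold all but requires, so it adds no evidence. Over all probe sets tested they did not overlap in 8.67%, where chance gives 10%. The largest fall was in an unnamed probe set, from 1596 ± 189 to 31.1 ± 4.27 (SD, n = 3 each), and another unnamed probe set fell from 598 ± 78.7 to 26.5 ± 5.02. Both are outside the rule for named genes and were chosen after their values were seen. Without wild type replicate 2 or without wild type replicate 3 the count was 13, all of them among the 31 and lower. With the replicate number as a block it was 11, also all among the 31 and lower. Of the control genes read at both ends, GAPDH had 3' to 5' signal ratios of 1.409, 1.079 and 1.101 on wild type replicates 1, 2 and 3. On the mutant arrays they were 1.405 to 1.559, so the genotypes overlapped narrowly and only through wild type replicate 1. Ubiquitin had 2.72 to 3.25 on the wild type and 2.33 to 2.91 on the mutant arrays. Actin had 8.35 to 11.1 and 9.10 to 9.94, so that the genotypes overlapped in both of these.

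**Figure D2:**
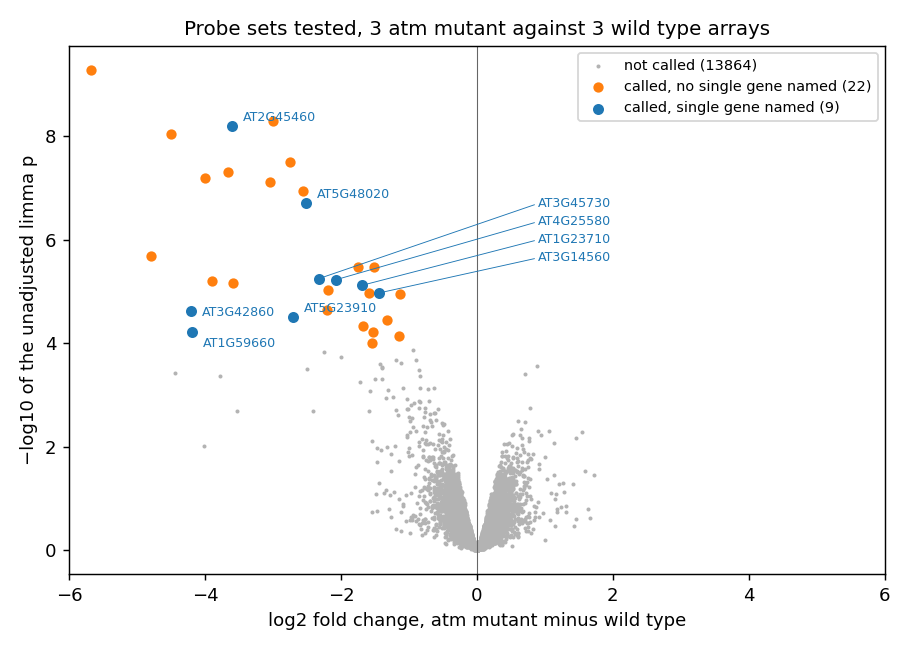
Log2 fold change of atm mutant minus wild type against the negative log10 of the unadjusted limma p for the 13895 probe sets tested, 1 point each. The 31 called probe sets all lie on the left, lower in the mutant, and the 9 with 1 named gene carry their locus.

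No probe set was called higher in the atm mutant with limma (0 of 13895), while 167 were higher and 300 lower at an unadjusted p under 0.05, against 695 in all expected by chance. Array weights gave 5 higher calls, the term for the 2 arrays 16, and the other 4 arrays alone 76. Among named genes, ndhE, a plastid gene for a subunit of the NADH dehydrogenase-like complex, had the smallest p of those above zero, with 140 ± 5.58 in the wild type and 260 ± 34.8 in the mutant (SD, n = 3 each). Its log2 change was 0.88 (SE 0.14, adjusted p = 0.0964), and the adjusted p ranged from 0.00227 to 0.638 over 18 alternatives. It passed the threshold in 3 of them, which were these same fits (0.0169 with array weights). The next were AT4G30330 with a log2 change of 0.60 (adjusted p = 0.52), AT5G65610 with 1.06 (adjusted p = 0.693), the plastid ribosomal protein gene rps16 with 0.90 (adjusted p = 0.693) and AT2G07170 with 0.94 (adjusted p = 0.758).

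Loci known for their response to ionising radiation were lower together. Of the 30 loci in this added list 15 were named on the array and 12 tested, and 12 of 12 had lower mean log2 signal in the atm mutant, with changes from -3.61 to -0.78 and a mean of -1.70. AT4G25580, AT5G60250 and AT4G22960 lay below the 40th percentile on every mutant array. They passed the filter only through the wild type, which all but fixed their direction. AT2G45460, AT5G48020, AT3G45730 and AT4G25580 were the 4 called over all probe sets, and 12 passed when adjusted over the list alone. AT5G60250 (log2 change -2.42, SE 0.53), AT2G18600 (-1.33, SE 0.27) and AT2G47680 (-1.23, SE 0.24) did not pass over all probe sets, with adjusted p of 0.391, 0.277 and 0.263. Camera gave the list an adjusted p of 2.2e-36 with the preset correlation, and adjusted p = 0.00256 with an estimated correlation. The estimate was -0.0059, below the preset 0.01, so a higher correlation does not account for the larger p. With a preset value camera takes its degrees of freedom from the number of probe sets, not of arrays. The value of 2.2e-36 therefore does not measure replication between arrays. Fry, which asks whether the members move one way, gave an adjusted p of 7.4e-05. The list was recalled from published irradiation studies and is not independent evidence of its direction.

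**Figure D3:**
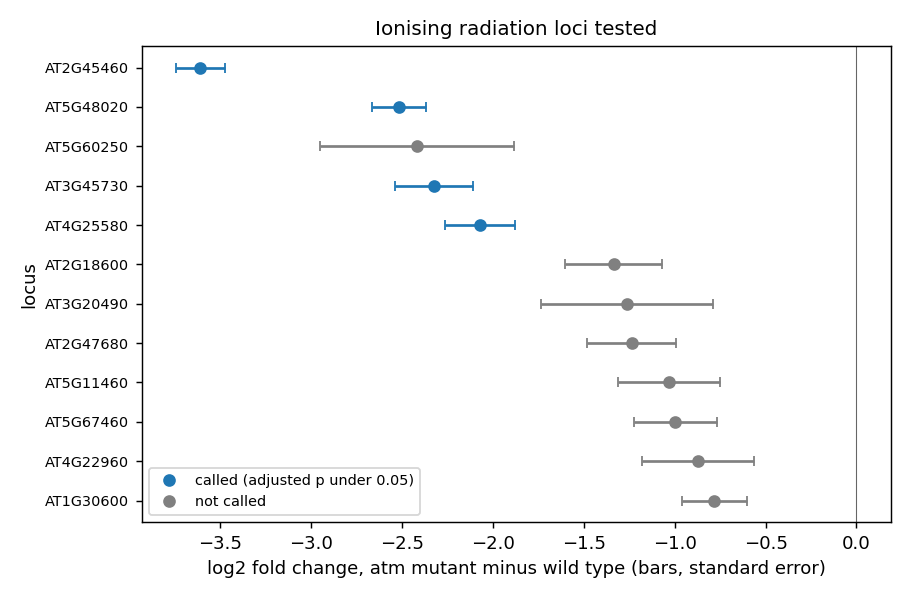
Log2 fold change of atm mutant minus wild type for the 12 ionising radiation loci tested, with standard errors from limma as bars. All 12 lie below zero, from -3.61 to -0.78, and the 4 called over all probe sets are in blue.

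Of the 265 members of the lists fixed beforehand, 27 were named on the array and 19 tested by name. Limma called 0 of them over all probe sets, 2 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. That 1 was ATMND1, a meiotic recombination gene in the list of the DNA damage response and homologous recombination, with a signal of 35.5 ± 4.09 in the wild type and 12.2 ± 4.26 in the atm mutant (SD, n = 3 each). Its log2 change was -1.59 (SE 0.35), with limma adjusted p = 0.388 over all probe sets and 0.00408 over the list alone, and it was -0.70 with a pseudocount of the 40th percentile. The only other member tested by name was AT1G48360, the nuclease gene FAN1, with a log2 change of -0.11 (SE 0.18). This list had 38 members, of which 5 were named on the array, and 21 of the 31 calls over all probe sets were unnamed here. Members without a named probe set may be among the unnamed ones, called or not. Names covered 27 of the 265 members but 13513 of all 22746 probe sets, a far larger share. The counts therefore do not show that the other members were unchanged. Of the list for end joining, excision and mismatch repair, ATLIG4, which encodes DNA ligase IV, had a log2 change of -0.52 (SE 0.25) and RAD4 0.27 (SE 0.15), neither past the threshold.

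None of the 5 members of the cell cycle lists tested by name was called over all 6 arrays. The G2 and mitosis list has 31 members and the S phase and replication list 27, and 3 of each were named on the array. Most members are therefore not covered. In the G2 and mitosis list the Aurora kinases AUR1 and AUR2 had log2 changes of 0.12 (SE 0.24) and -0.05 (SE 0.19), and the 3 tested members gave a camera adjusted p of 0.918. In the S phase and replication list PRL, which encodes MCM7, had 0.08 (SE 0.19) and ICU2, a DNA polymerase alpha subunit, 0.05 (SE 0.31). Of the abscisic acid, cold and drought list, COR47 had a log2 change of 0.37 (SE 0.24) and COR15A 0.30 (SE 0.31), with a camera adjusted p of 0.178 for 3 members. With the term for wild type replicate 1 and atm mutant replicate 2 this adjusted p was 0.0295, the lowest of 21 alternatives, which reached 0.585. On the other 4 arrays alone limma called COR47 (log2 change 0.47, adjusted p = 0.0155). The change of COR15A ranged from -0.10 to 0.59 over 18 alternatives.

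Of the oxidative stress list, GSTU25 had a log2 change of -0.44 (SE 0.16) and STZ, the zinc finger factor ZAT10, -0.73 (SE 0.84). Camera gave 3 members a mean of -0.43 and an adjusted p of 0.0839, or 0.272 with an estimated correlation. The adjusted p was 0.00603 with the term for the 2 arrays, the lowest of 20 alternatives, which reached 0.467. Over the alternatives the mean ranged from -0.643 to -0.11, and the change of STZ from -1.44 to 0.178. STZ had signals of 307.3 on wild type replicate 1 and 139.6 on atm mutant replicate 2, against 30.8 to 50 on the other 4 arrays. Single members stood for the circadian clock, with GI at 0.15 (SE 0.21), and for photosynthesis, with RCA, Rubisco activase, at 0.08 (SE 0.16). The root markers PYK10 and EXPA7 had log2 changes of 0.07 (SE 0.12) and -0.18 (SE 0.30). No member was tested by name of 6 lists, those for cell death, salicylic acid and pathogen defence, jasmonate and wounding, heat shock, seed and embryo markers, and flower markers.

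Of the other 14 added lists, which hold 187 tested genes, limma called 0 genes over all probe sets, with 12 at an unadjusted p under 0.05. Adjusted over its list alone, limma p was 0.0122 for ATMND1, 0.0469 for GSTU22 and 0.0181 for ndhE. With the 4 arrays limma called 5 plastid-encoded genes, 1 glutathione S-transferase and 1 UDP-glycosyltransferase. The plastid-encoded genes had a mean log2 change of 0.18, with 50 of 67 above zero, and a camera adjusted p of 2.5e-06. With an estimated correlation this was adjusted p = 0.567, and without wild type replicate 2 the mean was 0.07 and the camera adjusted p 0.223. Camera adjusted p was 0.486 for the repair and recombination genes by name, histones, glutathione S-transferases, WRKY factors, UDP-glycosyltransferases, beta-glucosidases and nuclear photosystem proteins. It was 0.74 for Aurora kinases and kinesins, 0.78 for cytochrome P450, expansins and xyloglucan enzymes and peroxidases, 0.929 for genes named LCR or PDF, of which PDF1A and PDF1B encode peptide deformylases and the others defensin-like proteins, and 0.97 for auxin genes. For the repair and recombination genes by name, trimmed by hand after a first comparison had been seen, fry gave an adjusted p of 0.245 for change in one direction and 0.0145 for change in either over 6 tested genes, and camera adjusted p = 0.567 with an estimated correlation. ATMND1 had the smallest p of the 6.

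The arrays did not fall by genotype alone. Across the tested probe sets, which are not independent replicates, wild type replicate 1 correlated with atm mutant replicate 2 at a Pearson r of 0.965 on the log2 scale, and with the other wild type arrays at 0.926 and 0.93. The deviations of these 2 arrays from their group means correlated at 0.647. Their 25S ribosomal RNA control signals were 836 and 2123, against 4106 to 5400 on the other 4 arrays. With the other 4 arrays alone, a fit added after seeing the data, limma called 233 probe sets, 157 lower and 76 higher in the atm mutant, and these included all 31 of the calls made with 6 arrays.

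**Figure D4:**
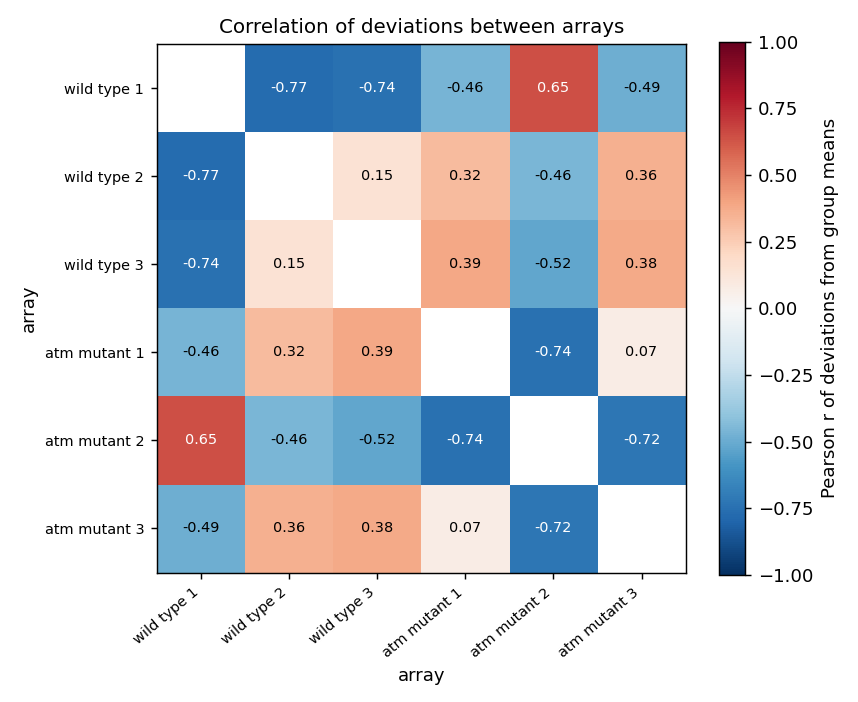
Pearson correlation across the tested probe sets between the deviations of each pair of arrays from their group means, with the diagonal left blank. Wild type replicate 1 and atm mutant replicate 2 reach 0.647, the highest of the pairs, and values within a genotype are lowered because the deviations of its 3 arrays sum to zero.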

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

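The term for the 2 arrays that deviated together and the fit to 4 arrays were chosen after the results had been seen, as was which of the added gene lists to keep, except the ionising radiation loci. All 31 calls stayed lower in the atm mutant, where tested, under every alternative. Array weights gave 73 calls, 68 lower and 5 higher, of which 57 reached 2-fold, 56 lower and 1 higher. The term gave 108, 92 lower and 16 higher, with 62 at 2-fold or more, 59 lower and 3 higher. The 4 arrays gave 233, 157 lower and 76 higher, with 68 at 2-fold or more, 60 lower and 8 higher. Each of these included all 31. Leaving out 1 array at a time gave 13 to 36 calls, 13 to 35 lower and 0 to 1 higher, the 1 without atm mutant replicate 2 and also over 2-fold. The other alternatives apart from the replicate block gave 28 to 34 calls, all lower. The cause of the higher and lower counts was not tested.

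Same-numbered arrays had deviations that correlated at -0.461, -0.46 and 0.379, so the largest shared deviation did not follow the replicate numbers. These values cannot tell whether the numbers pair the samples. The deviations sum to zero within a genotype, and 2 arrays with different numbers dominate them. With the number as a replicate block 11 probe sets were called, all among the 31 and lower, all at least 2-fold, and AT2G45460 and AT5G48020 were the named genes called. Of the ionising radiation loci 2 were called with the block and 7 each with the term and with the 4 arrays, while their mean log2 change ranged from -2.01 to -1.16 over the alternatives, past the threshold in all. For the plastid-encoded genes camera with an estimated correlation and fry left a mean of 0.18 short of the threshold, and 0.07 without wild type replicate 2; 5 of them were called with the 4 arrays. No probe set was named for ATM or XRI1, so no alternatives could be given for them by name. The fold changes of AT3G42860 and AT1G59660 depend on the floor chosen for low signals.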

Other observations

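Apart from quantile normalization and the pseudocount, which were planned as alternatives, the tests in this part were chosen after the results had been seen. With a term for wild type replicate 1 and atm mutant replicate 2, 46 probe sets with 1 named gene were called, 41 lower and 5 higher in the atm mutant. Of these, 37 were not called without the term, 32 lower and 5 higher. The largest fall among the 37 was in AT1G17360, at -2.25 (limma adjusted p = 2.6e-06 with the term and 0.0619 without), and the largest rise in AT4G12490, at 1.47 (0.00888 with the term and 0.825 without). Another 3 are given as single genes, picked after their values were seen and not tested as a group. AT1G49980, which encodes DNA polymerase kappa, a polymerase that copies past damaged bases, had a log2 change of -1.39 (limma adjusted p = 0.00908 with the term and 0.141 without). AT1G80850, of the DNA glycosylase superfamily, had -1.40 (0.00128 with the term and 0.1 without). SIM, the cyclin-dependent kinase inhibitor SIAMESE, had -0.76 (0.0163 with the term and 0.393 without).

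All 31 calls were lower in the atm mutant. A difference in scaling between arrays is argued against. Array medians lay between 40.05 and 41.36, while the 31 calls fell by at least 2.18-fold. Quantile normalization left 100% of the calls lower, but between such similar arrays it could hardly have reversed falls of this size. Noise of values near background is argued against as the whole cause. With a pseudocount of the 40th percentile, which damps low values, 34 probe sets were called lower, all 31 among them. The real split gave 31 calls and the highest of the other splits 0. Only 1 of the 10 splits gave as many as the real one, but 10 splits are too few for a share under 0.05. Every other split mixes the genotypes, so a difference between them widens the spread within its groups and hinders calls. The splits therefore cannot tell whether chance produced the calls. A candidate explanation is that these transcripts need ATM for their level in the wild type, whether or not the plants were irradiated, which the labels do not say. This stays an untested hypothesis: a second allele, a complemented line or an irradiated and unirradiated pair would bear on it and none was analysed here, and other differences between the seed lines, their cultures or the quality of their RNA stay open.

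Wild type replicate 1 and atm mutant replicate 2 deviated together from their groups. A swap of genotype labels is argued against by the probe sets called at 4-fold or more on the other 4 arrays. In 23 of 24 both arrays lay nearer to their own genotype. A wrong replicate number would leave this result unchanged and stays open. RNA degradation and a fault of hybridisation or scanning stay open: 0 of 3 control genes had a 3' to 5' ratio that set both arrays apart, ubiquitin by a narrow margin, and 0 of 2 spike controls did, but the 25S ribosomal RNA signal did, at 836 and 2123 against 4106 to 5400. Handling, harvest time or growth of these samples could also differ from the rest, and the labels record none of these. No biological explanation was tested, because no group in the labels joins these 2 samples.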
